A study of Mus musculus with 2 samples.

How the data were processed

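Intestinal RNA was measured by sequencing in 2 pooled samples of mice that carry the Min mutation of Apc: a control pool and a knockout pool in which Setd2 was deleted in the intestinal epithelium. Per the labels, the mice were 2 months old and each RNA sample was a mixture from 3 littermates, so each genotype had 1 library. Per the submitters' processing notes, reads were aligned to the mouse build mm10 with BWA and Bowtie2 and quantified with RSEM, and the tool versions were not given. Per the file headers, the sample files list for each gene the deposited expected counts and the deposited FPKM (fragments per kilobase of transcript, scaled by the authors to the mapped total). The authors' FPKM have 2 decimals, and genes below 0.01 are not listed. The deposited series table holds the same FPKM, with 0 where a sample file lists no value, and no comparison columns. Expected counts were whole numbers for 78.1% of the genes listed in the control pool and 78.2% in the knockout pool; RSEM divides reads that fit several genes among them, which gives the others. A count was taken as whole when its listed value, given to 2 decimals at most, had no remainder.

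The series table has 18919 genes, of which 617 were at 0 in both libraries. Expected counts added up to 8809678 in the control library and 8646358 in the knockout library. Gene symbols that a spreadsheet had turned into dates were repaired from the gene identifier for 26 genes. Positions came from the mouse reference annotation of the same build, which held 18871 of the gene identifiers. The 13 protein genes of the mitochondrial genome are not in the table, so the list of mitochondrial transcripts was not analysed here.

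Before the data were examined, a gene was counted as measured when its FPKM was 1 or more in at least 1 library, which held for 13253 genes. The compared value was the log2 ratio of knockout over control after a pseudocount of 1 FPKM was added to both. A gene was called at least 2-fold higher when this ratio was 1 or more and at least 2-fold lower when it was -1 or less. With 1 library per group there is no replicate check of any difference, and no p-value, standard error or paired test was computed. For single genes, the ratio of expected counts, each scaled to the library total (CPM), is given with a 95% interval, from the exact Clopper-Pearson interval of the knockout library's share of the rounded counts. These intervals, and floors of 3 counts per library (0.341 CPM in the control library and 0.347 CPM in the knockout library), cover counting error only, not differences between mice or pools. Where a gene had 0 counts in a library, its fold is a lower bound computed against that floor.

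Before the data were examined, 54 gene lists with 1221 genes were written, for cell types, intestinal regions, other tissues, signalling pathways, stress responses, metabolism and chromatin; lists share genes. For each list with at least 3 measured members (52 lists), the median log2 ratio was given with a 95% interval from binomial order statistics and set against 10000 random lists of the same size, matched on mean log2 FPKM in 20 bins. A list was said to stand apart when its percentile among the random lists was under 2.5 or over 97.5; by this rule alone 2.6 of the lists would stand apart by chance if lists were random genes. Genes are not replicates, and a percentile describes these libraries only. Lists written after the values had been seen are named as such where they are used.

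Genes named in the text follow a rule set before the data were examined. It takes Setd2, Apc, Ctnnb1 and Dvl2, then the 10 genes with the highest and the 10 with the lowest log2 ratio among genes with an FPKM of 5 or more in the higher library, and then, for each list described, up to 2 members with the highest and 2 with the lowest log2 ratio and the member with the highest mean FPKM. Of the 10 lowest genes, 8 had 10 or fewer expected counts in the higher library. Any other gene is named as chosen after its values were seen.

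The rule and the intervals were tested on simulated data with the depth and expression of these libraries, in which 13253 genes were drawn and 50 genes were set to each of several fold differences. Of the 13053 genes simulated with no difference, 0.613% were called, 0 of them with 50 or more expected counts. At a true fold of 3, 94% of the 50 genes were called, at 4-fold 86%, at 2-fold, where the true fold equals the threshold, 14%, and at 1.5-fold 0%, with 1 gene called in the wrong direction. Counting intervals held the true ratio for 95.8% of the genes with no difference. Of 200 lists of 25 unchanged genes, 5% stood apart. Those lists were random genes with independent counts, for which the percentile rule itself sets a share near 5%. The result therefore does not show how often lists of genes expressed together stand apart between 2 pools. The simulation holds counting error and no variation between mice.

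Alternatives set before the data were examined were pseudocounts of 0.1 and 0.01, no filter, a filter of FPKM 5, rescaling to TPM, scaling by the median ratio, scaling without the 50 most abundant genes, thresholds of 4-fold and 1.5-fold, the counting interval as an added condition, list means and random lists that were not matched. Chosen after seeing the data were a minimum of 50 expected counts in the higher library, leaving out the pancreas, stomach, liver and erythrocyte lists, and leaving out genes shorter than 300 nt. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.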

Results

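The data are gene expression profiles of the intestine of Apc-Min mice, a strain with a truncating mutation of the tumour suppressor Apc that develops intestinal adenomas. The control pool carried this mutation only, and the knockout pool also lacked Setd2 in the intestinal epithelium, while other cell types kept the gene. Setd2 encodes the enzyme that trimethylates lysine 36 of histone H3. Each genotype had 1 library, made from the mixed RNA of 3 littermates at 2 months of age, so no difference reported here has a replicate check. The control library held 8809678 expected counts and the knockout library 8646358, and 12504 and 12932 genes reached an FPKM of 1. The comparison of the pools asks how gene expression in the Apc-Min intestine differs when the epithelium lacks Setd2.

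Setd2 itself (gene identifier 235626, mm10 chromosome 9, 110532500 to 110618633) was lower in the knockout pool, at 3.47 FPKM against 6.87. Its expected counts were 254 against 513, a ratio of 0.504 after scaling to the library totals (95% counting interval 0.432 to 0.587), and its log2 ratio of -0.82 did not reach the 2-fold rule. The gene value sums reads over the whole transcript and over epithelial and other cells. Apc, the mutated tumour suppressor, was at 10.51 FPKM in the control pool and 10.73 in the knockout pool, a ratio of 1.02 (0.940 to 1.11). Ctnnb1, which encodes beta-catenin, the transcriptional effector of Wnt signalling that Apc restrains, was at 229.9 and 236.8 FPKM, a ratio of 1.03 (0.9997 to 1.07). Dvl2, which relays Wnt signals from the receptors (chromosome 11, 70000592 to 70010109), was at 2.19 and 2.62 FPKM, from 57 and 67 counts; the interval of its ratio, 0.829 to 1.74, includes 1. For Apc, Ctnnb1 and Dvl2 no difference of 2-fold was present, and the signs for Apc and Ctnnb1 turned when the libraries were scaled by the median ratio, to -0.03 and -0.02.

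Across the 13253 measured genes, 369 were at least 2-fold higher in the knockout pool and 170 at least 2-fold lower, and 12714 (95.9%) lay within 2-fold. Among the genes past 2-fold, 68.5% were higher. The counting interval of the ratio excluded 1 for 298 of the higher and 102 of the lower genes. The 10 genes with the highest ratios included 9 digestive enzyme genes of the exocrine pancreas list. The other, Tmem254b, had 0 counts in the control pool and 500.7 in the knockout pool, but its near-identical neighbour Tmem254c was lower, at 10.22 FPKM against 50.09, and reads that fit both genes leave each value uncertain. Together they had 626.9 and 611.9 counts, a ratio of 0.994 (0.888 to 1.11), so the sum did not differ detectably. Of the higher and lower genes, 65 and 62 had transcripts shorter than 300 nt. The median log2 ratio of all measured genes was 0.08. The counts depend on how low values were treated: with a pseudocount of 0.1 they were 699 and 282, and with at least 50 expected counts in the higher library, a condition chosen after seeing the data, 216 and 80.

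**Figure D1:**
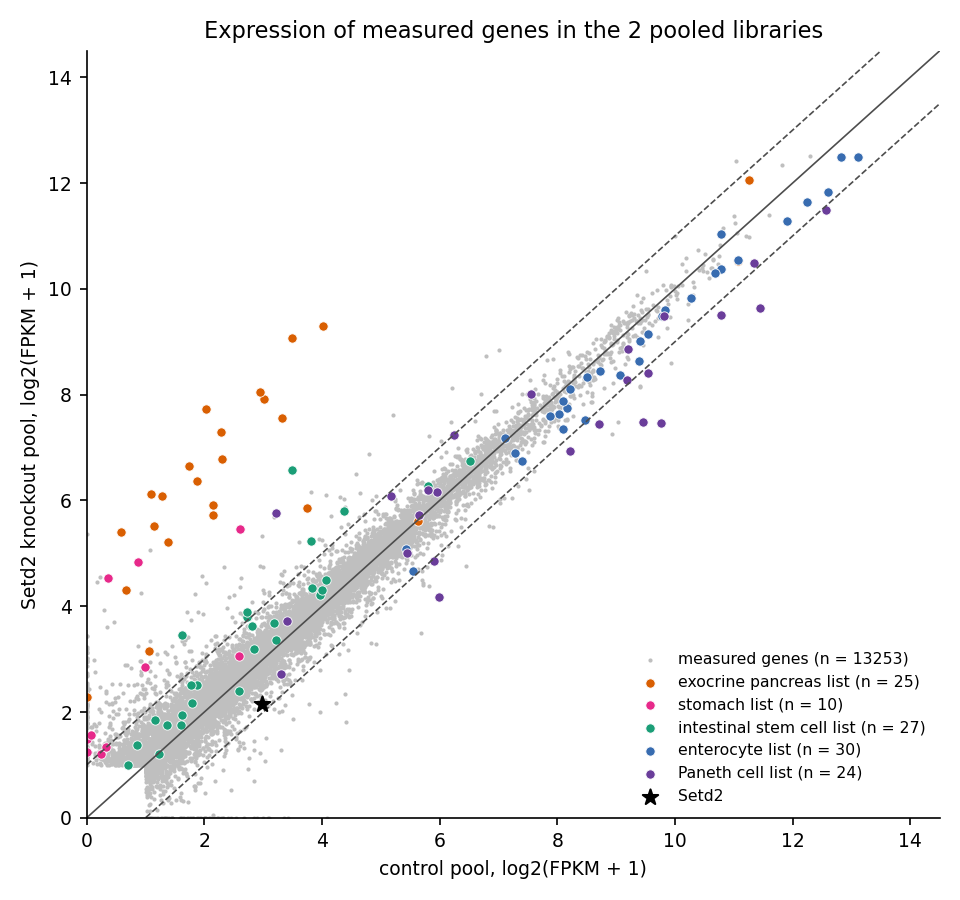
Log2 of FPKM plus 1 for each of the 13253 measured genes in the control pool (x axis) and in the knockout pool (y axis), with members of 5 lists coloured, Setd2 as a star, a solid line at equal values and dashed lines at 2-fold. Of the genes, 369 lie on or above the upper dashed line and 170 on or below the lower; 21 of the 25 pancreas genes are among the first and 10 of the 24 Paneth genes among the second.

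Genes of the crypt base and targets of Wnt signalling were higher in the knockout pool. Among 27 measured markers of intestinal stem cells, 6 were at least 2-fold higher, 0 lower, and 25 had a log2 ratio above 0 (24 when scaled by the median ratio). Gkn3, a gastrokine that the stomach also makes, was at 93.88 FPKM against 10.3, 9.11-fold higher (7.11 to 11.8), and Ephb3, a receptor that positions crypt cells, was at 9.94 against 2.09. Olfm4, an abundant stem cell transcript, was at 106.02 against 90.98, and the lowest ratios were those of Bmi1 (4.28 against 5.04) and Tnfrsf19 (1.31 against 1.34). Lgr5, the receptor that marks crypt base stem cells, was at 2.37 against 1.59 FPKM and was chosen after its values were seen. The median log2 ratio of the list was 0.47 (95% interval 0.31 to 0.75), above all 10000 matched random lists. Of 29 measured Wnt targets, 5 were at least 2-fold higher, 0 lower, and 22 had a ratio above 0, with a median of 0.50 (0.25 to 0.70) at percentile 100. In other lists too are 15 of them, and 23 of the 29 had an FPKM of 1 or more in the control pool. Notum, a secreted Wnt inhibitor induced by Wnt signalling (chromosome 11), was at 5.84 FPKM against 0.9, 6.495-fold higher (3.81 to 11.8). Mmp7, a protease made by Paneth cells and by adenomas, was at 31.13 against 42.64, Tcf7, which encodes a Wnt transcription factor, at 2.86 against 3.63, and Ppard, the most abundant member, at 63.88 against 65.15. Axin2 (12.90 against 5.59) and Cd44 (13.80 against 5.58) were also higher and were chosen after their values were seen. Among components of the Wnt pathway, 0 of 28 were past 2-fold after the pseudocount was added. Their median was 0.27 (0.03 to 0.42) at percentile 99.8, which was 81.5 among genes with an FPKM of 5 or more. Their highest ratios were those of the receptors Fzd8 (2.74 against 1.01) and Fzd1 (3.31 against 1.71). Without the pseudocount Fzd8 was past 2-fold, with a count ratio of 2.72 (1.77 to 4.28). The lowest ratios were those of Dvl1 (22.23 against 31.29) and the receptor Fzd5 (16.25 against 18.02). Transcripts of pancreas, stomach and blood were higher in the same pool, with list medians of 4.38, 1.49 and 1.68.

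Proliferation genes, ribosomal protein genes and targets of YAP shifted in the same direction. All 35 measured proliferation genes had a log2 ratio above 0 as deposited (34 when scaled by the median ratio, where Mcm3 was at -0.002), with a median of 0.41 (0.29 to 0.46) at percentile 100, though 1 alone was past 2-fold. That was Mcm2, a subunit of the replicative helicase, at 18.67 FPKM against 7.03, 2.66-fold higher (2.26 to 3.13). Cdc20, an activator of mitotic exit, was at 21.06 against 11.22 and Pcna, the replication clamp, at 126.7 against 77.99, while Mcm3 (9.88 against 9.46) and Tyms, which makes thymidylate (24.72 against 23.42), differed least. All 33 ribosomal protein genes were above 0 as deposited and under the 3 scalings tried, with 0 past 2-fold and a median of 0.24 (0.21 to 0.26) at percentile 100; Rplp1 was at 1420 FPKM against 1117, Rps2 at 905.8 against 701.9 and Rpl38 at 469.1 against 443.1. Of 16 Hippo and YAP targets, 2 were at least 2-fold higher and 15 were above 0, with a median of 0.31 (0.19 to 0.58) at percentile 99.4. Those were Clu, an extracellular chaperone that marks regenerating crypts, at 195.2 against 35.79 FPKM, 5.45-fold higher (4.99 to 5.97), and Anxa1, at 22.05 against 5.16. Il33 (17.49 against 17.95) and Ly6a (22.72 against 21.32) of that list were close between the pools. The pancreas and stomach lists, with medians of 4.38 and 1.49, moved the same way as these groups.

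Other growth pathways did not stand apart as planned, but some did under alternatives. Of 16 Notch pathway genes, the target Hey1 was higher (3.8 against 0.97 FPKM), Jag2, a ligand, was at 2.66 against 1.19 and Hes6 at 50.77 against 36.36, with a list median of 0.29 at percentile 97.3. It stood apart higher in most alternatives, with percentiles from 91.8 for the mean to 99.1 for a pseudocount of 0.1. Among 22 genes of EGF and MAPK signalling, 2 were at least 2-fold higher, the transcription factor Etv5 (6.64 against 1.37) and the ligand Ereg (4.57 against 1.55). Erbb3, a receptor of the same family, was at 49.35 against 75.3, and the median of the list was 0.23 at percentile 97.1, which ranged over alternatives from 56.4 with a filter of FPKM 5 (median 0.11) to 98.7 with a pseudocount of 0.01. The BMP and TGF-beta list had 25 measured genes, 0 past 2-fold after the pseudocount and a median of 0.08 at percentile 44.8. Bmp7 was at 3.52 against 1.51, with a count ratio past 2-fold (2.33, 1.67 to 3.36). Bmp2 was at 8.52 against 11.61 and the BMP target Id1 at 103.3 against 105.2. In the list for epithelial-mesenchymal transition and invasion, 0 of 21 genes were past 2-fold and the median was 0.17 at percentile 94.2 (from 60.5 with a filter of FPKM 5, median 0.07, to 98.8 with TPM), with Krt18 at 180.4 against 96.61, Mmp14 at 24.41 against 12.63, Krt20 at 1174 against 1522 and Krt8 at 1821 against 1740.

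**Figure D2:**
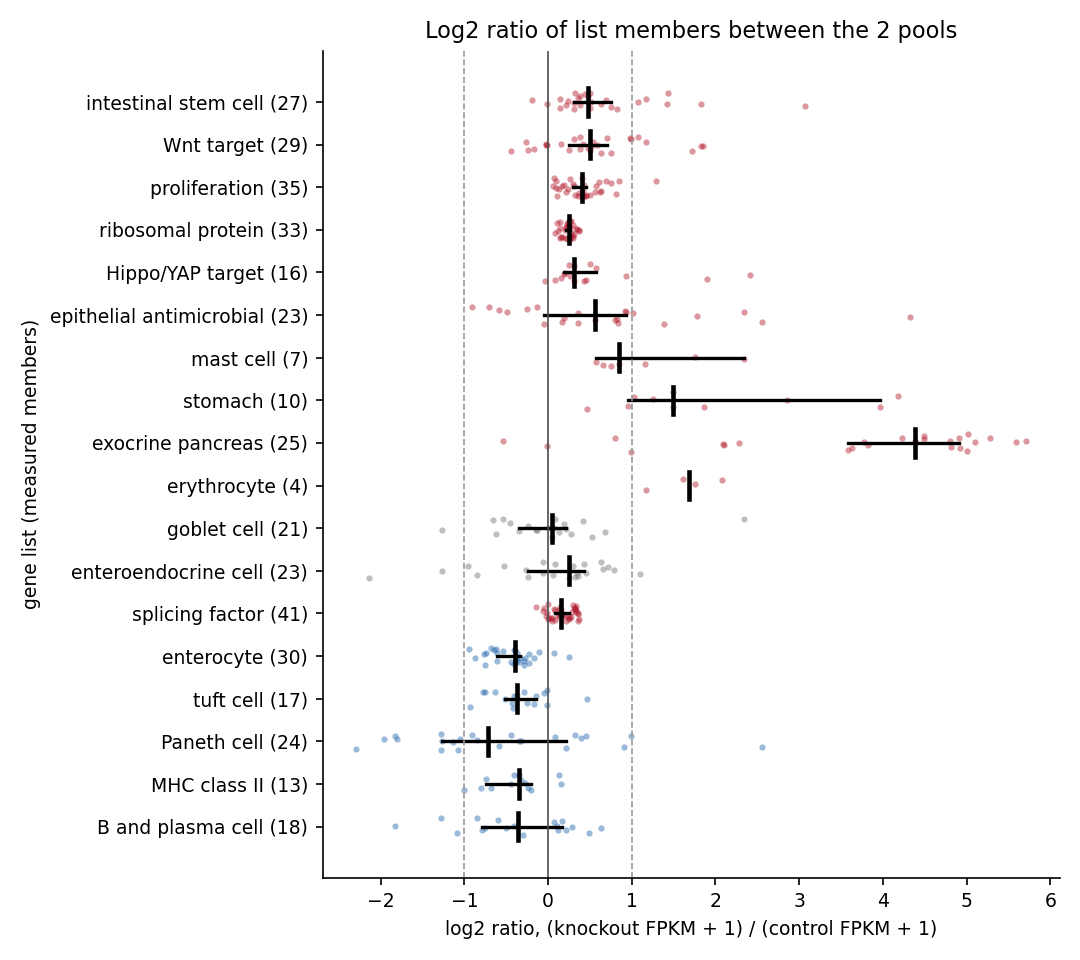
Log2 ratio of knockout over control (x axis) for the measured members of 18 gene lists (y axis) with their number in brackets; each point is a gene, the upright bar the median and the line its 95% interval, which fewer than 6 members do not give. Points are red where the list stood apart higher, blue where lower and grey where it did not, and dashed lines mark 2-fold. The exocrine pancreas, stomach and erythrocyte lists lie far to the right, the stem cell, Wnt target and proliferation lists to the right of 0, and the enterocyte, tuft and Paneth lists to the left.

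Markers of absorptive enterocytes were lower in the knockout pool. Of 30 measured markers, 28 had a log2 ratio below 0, as deposited and under the 3 scalings, and for 28 the counting interval lay below 1, but 0 were past 2-fold as deposited; 7 of the 30 are in other lists too. Their median was -0.39 (-0.62 to -0.33) at percentile 0, and their summed FPKM was 33777 against 47287. Apoa4, an apolipoprotein of chylomicrons and the most abundant member, was at 5765 FPKM against 8881, a ratio of 0.649 (0.643 to 0.655). Ace, a brush border peptidase, was at 183.3 against 355.04, and Nt5e, an ectonucleotidase, at 24.5 against 45.73. The members above 0 were Alpi, intestinal alkaline phosphatase (2110 against 1770), and Slc7a9, an amino acid transporter (143.6 against 136.8). Tuft cell markers were also lower, with 16 of 17 below 0 and a median of -0.37 (-0.52 to -0.14) at percentile 0. After the pseudocount 0 were past 2-fold. Ltc4s, which makes leukotriene C4, was at 4.23 against 8.99 FPKM (count ratio 0.479, 0.282 to 0.793). Lrmp was at 6.79 against 12.36, Avil at 9.73 against 6.8, Ptgs1 at 11.21 against 11.28 and Cd24a at 83.13 against 84.18.

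Secretory lineage markers went both ways. Of 21 measured goblet cell markers, 1 was at least 2-fold higher and 1 lower, and the median of 0.05 (-0.35 to 0.21, percentile 51.2) did not stand apart. Their sum was lower all the same, at 4416 FPKM against 5910, with a count ratio of 0.648 (0.641 to 0.656). Retnlb, a bactericidal goblet cell protein, was at 70.24 FPKM against 13.07, 5.37-fold higher (4.22 to 6.91), and Foxa3, a goblet transcription factor, was at 8.33 against 4.84. Clca1, a secreted mucus protease, was at 281.04 against 675.7, a ratio of 0.416, Muc2, the main mucin, at 48.45 against 76.78, and Zg16, a mucus lectin, at 1477 against 2152. Among 23 enteroendocrine markers, Gcg, the proglucagon gene, was at 0.63 against 6.21 FPKM (6 and 60 counts, ratio 0.102, 0.0360 to 0.235), Nts, the neurotensin gene, was at 0.57 against 2.78, and Scg5 was at least 2-fold higher, at 2.95 against 0.84. Pax4 (1.02 against 0.17) and Reg4 (105.6 against 82.22) were other members, and the list median of 0.25 at percentile 97.1 did not stand apart; its percentile ranged from 13.3 for the mean to 98.7 with TPM.

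Paneth cell transcripts, and alpha-defensins among them, were lower in the knockout pool. Of 24 measured Paneth markers, 10 were at least 2-fold lower and 1 was higher, with a median of -0.72 (-1.27 to 0.21) at percentile 0 and 16 members below 0. Defa24, an alpha-defensin and the most abundant member, was at 2860 FPKM against 6057, a ratio of 0.472. Gm15284 was at 176.02 against 866.3 and Gm14851 at 178.8 against 700.9, both defensin-like genes. Pla2g2a, a secreted antibacterial phospholipase (chromosome 4, start 138831857), was the member that was higher, at 53.51 against 8.27, 6.47-fold (4.88 to 8.71), and Clps, pancreatic colipase, was at 149.3 against 74.83 and belongs to the pancreas list as well, whose median was 4.38. Lyz1, the Paneth cell lysozyme, was at 716.2 against 897.3, and Defa23, a further alpha-defensin, at 790.3 against 2774; both were chosen after their values were seen. A division of the list by position was also chosen after the values were seen: the 15 members inside the alpha-defensin cluster (chromosome 8, 21025545 to 21735471) had 9 at least 2-fold lower and a median of -1.08 (-1.81 to 0.08). The 9 members outside it had 1 lower and 1 higher, a median of -0.32 (-0.91 to 0.99) and a mean of the opposite sign, 0.11. The upper limit of that interval is the log2 ratio of Clps, and Pla2g2a (2.56) lies above it. Both raise the mean. The summed counts of the 9 members had a ratio of 0.747 (0.732 to 0.762). The whole cluster had 25 genes in the table, 22 measured, of which 13 were at least 2-fold lower and 1 higher, with a summed FPKM of 7680 against 17932 and a count ratio of 0.428 (0.421 to 0.434). Reads are shared among these near-identical genes, so that values of single defensins are uncertain while the sum is less so.

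**Figure D3:**
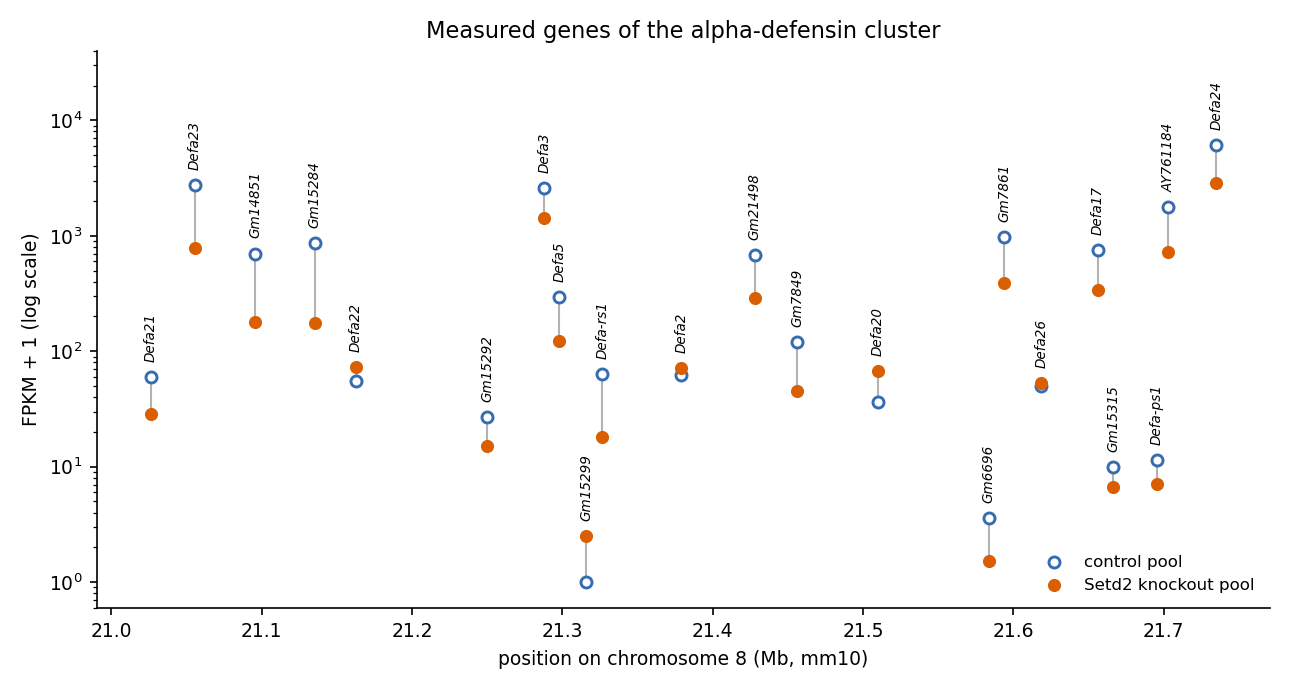
FPKM plus 1 on a log scale (y axis) of the 22 measured genes of the alpha-defensin cluster at their positions on chromosome 8 of mm10 (x axis, in Mb), with open circles for the control pool and filled circles for the knockout pool. Of these genes 13 were at least 2-fold lower in the knockout pool and 1 higher.

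Transport and region markers included genes that were higher and genes that were lower. Slc11a2, the apical iron importer, was at 278.2 FPKM against 73.17, 3.89-fold higher (3.73 to 4.06), and Cybrd1, the reductase that supplies its ferrous iron, was at 89.22 against 22.91, 3.89-fold (3.64 to 4.17). Slc40a1, the basolateral iron exporter ferroportin, was at 255.4 against 102.8, 2.48-fold higher. Transcripts of red cells were higher in the same pool, with Hbb-bs at 116.6 against 26.81. Slc11a2 and Cybrd1 were 2 of 3 genes at least 2-fold higher among 16 markers of proximal intestine, where 0 were lower. The median was -0.15 (-0.62 to 0.89) at percentile 2.16 and the mean was 0.14. The negative median was lost without a filter (0.04), after rescaling to TPM (0.002) and for the mean. In that list the hormone gene Gip was at 44.45 against 80.87, Lct, lactase, at 161.3 against 271.2, and Fabp1, the fatty acid binding protein, at 3179 against 4870. Of 30 brush border and transport genes, 3 were higher and 3 lower, with a median of -0.12 at percentile 0.78. Trpv6, a calcium channel, was at 7.57 against 3.1, the vitamin C transporter Slc23a1 at 1.44 against 8.9, the amino acid transporter Slc6a20a at 71.98 against 183.2, and S100g, a calcium carrier, at 1343 against 1555. Of 16 distal markers, 2 were lower, Naaladl1 (26.03 against 86.45, ratio 0.301) and Amn, of the vitamin B12 receptor (20.06 against 51.75). Fabp6, which binds bile acids, was at 1.68 against 0.47 and Reg3g at 1300 against 730.5, and the median of 0.06 had a mean of -0.12 and did not stand apart (percentile 59.8). Among 9 colon markers 1 was higher, Retnlb (70.24 against 13.07), which is a goblet marker too, and 3 lower, such as Car4 (44.79 against 113.9) and Ang4 (172.8 against 417.2), while B3galt5 was at 6.73 against 3.08, within 2-fold on the log2 scale used. The colon median of -0.22 at percentile 0.515 turned to 0.04 without a filter and 0.05 after rescaling to TPM. The 8 Hox and Cdx genes, which set position along the gut, had 0 past 2-fold and a median of 0.07 (percentile 40.6; without a filter -0.06 at percentile 1.92), with Cdx2 at 58.56 against 56.3, Cdx1 at 64.31 against 45.04 and Hoxa5 at 1.17 against 1.51.

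Antimicrobial and regeneration genes of the epithelium were higher as a list. Of 23 measured, 6 were at least 2-fold higher, 0 lower and 7 below 0, with a median of 0.56 (-0.05 to 0.93) at percentile 100, and 11 are also in another list. Of the 6 higher genes 3 had a control FPKM below 1, so those counted as measured only through the knockout pool. Reg3b, an antibacterial lectin and the most abundant member, was at 5469 FPKM against 2088, 2.62-fold higher (2.57 to 2.67). Reg2 had 1 count in the control pool and 130 in the knockout pool, a ratio of 132 (23.4 to 5271), and is a gene of the regenerating islet family that pancreas also expresses. Retnlb and Pla2g2a are members as well, and Itln1, an intelectin, was at 309.7 against 581.6. The pancreas and stomach lists were higher in the same pool, with medians of 4.38 and 1.49, and Reg1 is in the pancreas list too.

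Metabolic lists differed by less than 2-fold for most genes. Among 32 genes of xenobiotic metabolism the median was -0.13 at percentile 0.75, with Cyp2c29 at least 2-fold higher (62.99 FPKM against 27.82), the glucuronosyltransferase Ugt2b5 lower (8.89 against 27.56), Cyp2c55 at 54.58 against 28.75 and Cyp1a1 at 612.2 against 927.8. Cholesterol synthesis had 16 of 22 genes below 0, 0 past 2-fold and a median of -0.08 at percentile 0.59, with Msmo1 at 45.08 against 56.63 and Stard4 at 23.71 against 31.58. Fatty acid oxidation and PPAR targets had a median of -0.04 and a mean of 0.06 over 25 genes (percentile 6.90), with 2 at least 2-fold higher, Acot1 (6.18 against 0.97) and Cyp4a10 (7.86 against 2.32), and Acot12 at 13.07 against 25.44 and Slc27a4 at 225.4 against 343.5. Of 19 genes of fatty acid synthesis, Scd2, a desaturase, was higher (23.31 against 8.9), Fads2 was at 31.84 against 17.84, Mlxipl at 30.98 against 49.7 and Dgat2 at 320.4 against 393.4 (median 0.21, percentile 95.7, or from 89.4 for the mean to 98.3 with a pseudocount of 0.1). Glycolysis and hypoxia genes had 2 of 23 at least 2-fold higher, hexokinase Hk2 (6.23 against 2.21) and the glucose transporter Slc2a1 (18.17 against 7.55), with Gapdh at 2432 against 2083 (median 0.13, percentile 91.2, or from 74.1 among random lists that were not matched to 98.1 with at least 50 expected counts). Subunits of oxidative phosphorylation were within 2-fold, with a median of -0.06 over 28 genes (percentile 29.0, or 1.17 among random lists that were not matched) and Atp5b at 1345 against 1399. Among 17 clock genes Dbp, an output regulator, was lower (25.72 against 54.07), Per3 was at 5.1 against 9.16 and Arntl at 4.25 against 2.36 (median -0.01, percentile 9.70). The clock list stood apart lower with a filter of FPKM 5 (median -0.23, percentile 0.03), without a filter (percentile 1.58), with TPM (0.88), with at least 50 expected counts (0.10) and for the mean (0.77), and its percentile was at most 11.4 under the others.

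Immune markers differed by cell type. Mast cell genes were higher, with 3 of 7 past 2-fold and a median of 0.85 (0.57 to 2.35) at percentile 99.9. An FPKM of 1 or more in the control pool was reached by 3 of the 7. The others, such as Fcer1a (1.15 against 0.45), counted as measured only through the knockout pool, which favours a higher median. Mcpt1, a mucosal mast cell protease, was at 38.91 FPKM against 6.85, 5.68-fold higher (4.31 to 7.59), and Mcpt2 at 19.67 against 5.12. The B cell gene Ms4a1 (CD20) was lower, at 0.9 against 5.73, a ratio of 0.157, while in the same list of B and plasma cell genes Jchain, the most abundant member, was at 744.7 against 609.1, and the highest ratios were those of Sdc1 (44.23 against 28.17) and Derl3 (10.65 against 7.28). That list had 3 of 18 lower and a median of -0.35 (-0.79 to 0.17) at percentile 0, which turned to 0.13 among genes with an FPKM of 5 or more. Antigen presentation by class II had 11 of 13 genes below 0 and a median of -0.35 (-0.75 to -0.21) at percentile 0.04. H2-Ob, a gene of B cells, was lower (1.9 against 4.82), H2-Eb2 was at 0.68 against 1.94, Cd74, the invariant chain, at 584.1 against 690.9 and Ctss, a protease that trims it, at 134.7 against 121.1. T cell genes did not stand apart, with a median of -0.01, a mean of 0.01 and percentile 6.65 over 20 genes, Cd247 at 6.17 against 3.88, the kinase Lck at 5.24 against 8 and Gzma at 127.9 against 108.3. Neither did myeloid genes (22 measured, median 0.15, percentile 79.2), with S100a9 at 2.72 against 1.11 and Lyz2 at 76.97 against 107.7. Cytokines and chemokines did not (18 measured, -0.02, percentile 8.17), with Il11 at 3.38 against 1.39, Nos2 at 0.51 against 1.47 and Ccl5 at 109.5 against 80.42. Interferon response genes did not (35 measured, 0.05, percentile 26.9), with Mx1 past 2-fold at 8.92 against 3.66, Zbp1 at 52.81 against 30.1 and Psmb8 at 98.98 against 131.4.

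Fibroblast and matrix genes were slightly higher, and other stromal lists were mixed. Of 25 such genes, 24 were above 0 as deposited (19 when scaled by the median ratio) and 2 at least 2-fold higher, with a median of 0.25 (0.13 to 0.42) at percentile 99.2, which was 97.2 among genes with an FPKM of 5 or more. Mmp13, a collagenase, was at 6.71 FPKM against 2.19, Timp1, an inhibitor of such proteases, at 2.23 against 0.51 and Fbln1 at 40.86 against 66.21. Among 18 endothelial genes, Sox17, an endothelial transcription factor, was at 11.95 against 0.38, 32.9-fold higher (18.2 to 66.5), Cdh5, the endothelial cadherin, at 6.87 against 2.89 and Plvap at 39.11 against 34.47. The median of 0.26 did not stand apart (percentile 94.7, or from 88.2 with a filter of FPKM 5 to 98.7 for the mean). The 8 genes of enteric neurons and glia had a median of 0.47 at percentile 99.6, with Vip at 9.41 against 5.03 and Kit at 5.04 against 2.83, which turned to -0.01 without a filter and -0.02 after rescaling to TPM. Smooth muscle (18 genes, median -0.03, percentile 13.0), with Myl9 at 161.01 against 134.5, Ckb at 862.03 against 687.2 and Mylk at 55.04 against 61.8, and adipocyte genes (10 genes, -0.12, percentile 2.84), with Pck1 at 117.04 against 112.8 and Lipe at 33.27 against 43.32, did not stand apart. The adipocyte list did so, lower, with pseudocounts of 0.1 and 0.01 (percentiles 2.12 and 2.10), without a filter (0.80), with TPM (2.26), scaled without the 50 most abundant genes (2.22) and among random lists that were not matched (2.17), but was at 18.9 with a filter of FPKM 5.

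Transcripts of pancreas, stomach and red cells were higher in the knockout pool, with the highest medians of the fixed lists at a pseudocount of 1 FPKM. Of 25 measured genes of the exocrine pancreas, 21 were at least 2-fold higher and 0 lower, with a median of 4.38 (3.59 to 4.90) at percentile 100. The list took 0.759% of expected counts against 0.336%, and 22 of its genes had an FPKM of 1 or more in the control pool. Reg1 and Zg16, which the intestine expresses, made up 0.314% of the control counts and 0.407% of the knockout counts, and the other 23 genes 0.0219% and 0.352%, 16.1-fold higher (15.4 to 16.9). That separation was chosen after the values were seen. Ctrb1, a chymotrypsinogen, was at 537.7 FPKM against 10.21, 52.7-fold higher (42.1 to 66.8), and Amy2a5, the pancreatic amylase, was at 626.3 against 15.14. Cela2a, an elastase, was at 242.07 against 7.12, Cela3b at 99.51 against 2.33 and Cpa1, a carboxypeptidase, at 68.35 against 1.14. Trypsin genes share reads and are uncertain singly: Try5 was at 212 against 3.06, Try4 at 264.2 against 6.72, Prss2 at 155.4 against 3.88 and Prss3 at 41.09 against 0.5. Reg1 (4245 against 2444), Pnliprp2 (48.19 against 48.44) and Zg16 were the most abundant and the lowest members. Stomach genes were also higher, with 8 of 10 past 2-fold, all 10 above 0 as deposited and under the scalings, and a median of 1.49 (0.96 to 3.97) at percentile 100; 2 of the 10 had an FPKM of 1 or more in the control pool. Gkn1, a gastrokine of the stomach lining, was at 22.24 against 0.28 (232 and 3 counts, ratio 78.8, 26.6 to 385), Tff2, a trefoil peptide of gastric glands, at 27.58 against 0.83, Ctse, a gastric protease, at 43.14 against 5.08, Atp4a, of the gastric proton pump, at 1.31 against 0.19 and Cym at 7.3 against 5.02. Hemoglobin transcripts of red cells were higher for 4 of 4 genes (median 1.68, percentile 100): Hbb-bs was at 116.6 against 26.81, Hbb-bt at 20.99 against 8.74, Hba-a1 at 65.61 against 18.76 and Hba-a2 at 36.04 against 11.16, each uncertain singly because reads are shared. Of 3 liver genes 1 was at least 2-fold higher, Ttr (4.35 against 1.67), and Ambp was at 6.37 against 3.48; the median of 0.72 at percentile 98.2 went to 97.1 with a pseudocount of 0.1. Without the pancreas, stomach, liver and erythrocyte lists, a condition chosen after seeing the data, 335 genes were at least 2-fold higher and 170 lower. That removed list members only. Genes of gastric glands outside these lists stayed among the 335, such as Anxa10 and Muc6, which were chosen after their values were seen. The count therefore does not show how many of the higher genes come from other tissues.

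Genes in the lists of splicing factors, H3K36 enzymes and chromatin regulators stayed within 2-fold after the pseudocount was added. Of 17 genes in the list for H3K36 methylation 0 were past 2-fold (median 0.14, percentile 69.3). Setd2 itself had the lowest ratio of that list, with a count ratio of 0.504. Kdm2b, a demethylase, was at 5.16 FPKM against 3.4. Setd3, the most abundant gene listed, was at 44.83 against 44.33. Of 30 genes in the list of polycomb, trithorax and other chromatin genes 0 were past 2-fold (median 0.10, percentile 51.3). Dnmt3b, a DNA methyltransferase, was at 1.24 against 0.44 (count ratio 2.74, 1.51 to 5.21). Cbx8 was at 7.09 against 4.53, Jarid2 at 7.57 against 9.02 and Kdm6b at 17.82 against 17.42. Splicing factors had 34 of 41 genes above 0 as deposited (30 when scaled by the median ratio) and 0 past 2-fold, with a median of 0.15 (0.09 to 0.26) at percentile 98.8, which was 89.0 among random lists that were not matched. Psip1, a reader of H3K36 methylation, was at 7.81 against 5.81, Srsf6 at 46.07 against 35.63, Srsf11 at 27.19 against 30.29 and Hnrnpa2b1 at 197.5 against 190.5. The 9 measured replication histone genes went both ways (2 higher, 3 lower, median 0.01, percentile 22.8); Hist1h2bc was at 136.4 against 214.3, and Hist2h3c1 (6.76 against 0) and Hist2h3c2 (0 against 7.61) share reads and are uncertain.

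Stress programmes as lists did not stand apart. Among 22 p53 targets and DNA damage genes 2 were at least 2-fold higher (median 0.08, percentile 52.98): Cdkn2a, a tumour suppressor locus, with 0 counts in the control pool and 15 in the knockout pool (1.94 FPKM), at least 5.09-fold higher against the floor (lower limit of the interval 3.65), and Phlda3, at 9.26 against 3.31. Sesn1 was at 34.52 against 49.4 and Cdkn1a, the cell cycle inhibitor p21, at 132.4 against 133.9. Of 24 NRF2 and oxidative stress genes, the heme oxygenase Hmox1 was higher (6.68 against 1.12), Gstm3 was at 329.2 against 216.6, Gpx2 at 380.4 against 568.5 and Prdx1 at 635.7 against 779.1 (median 0.06, percentile 61.9). Unfolded protein response genes (21 measured, median 0.11, percentile 84.2) had Creld2 at 52.91 against 32.63, Atf3 at 15.82 against 26.12 and Calr at 409.9 against 326.4. Immediate early and heat shock genes (23 measured, median 0.06, percentile 45.5) had Hspa1a at 3.5 against 1.91, Hsp90aa1 at 140.02 against 98.17 and Hspa8 at 1057 against 974.1. As a check of the samples, Xist, transcribed from the inactive X chromosome, was at 26.15 FPKM against 32.37 and Tsix, its antisense gene, at 4.15 against 5.3, while each Y-linked gene of the list had 3 or fewer counts in each pool.

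**Figure D4:**
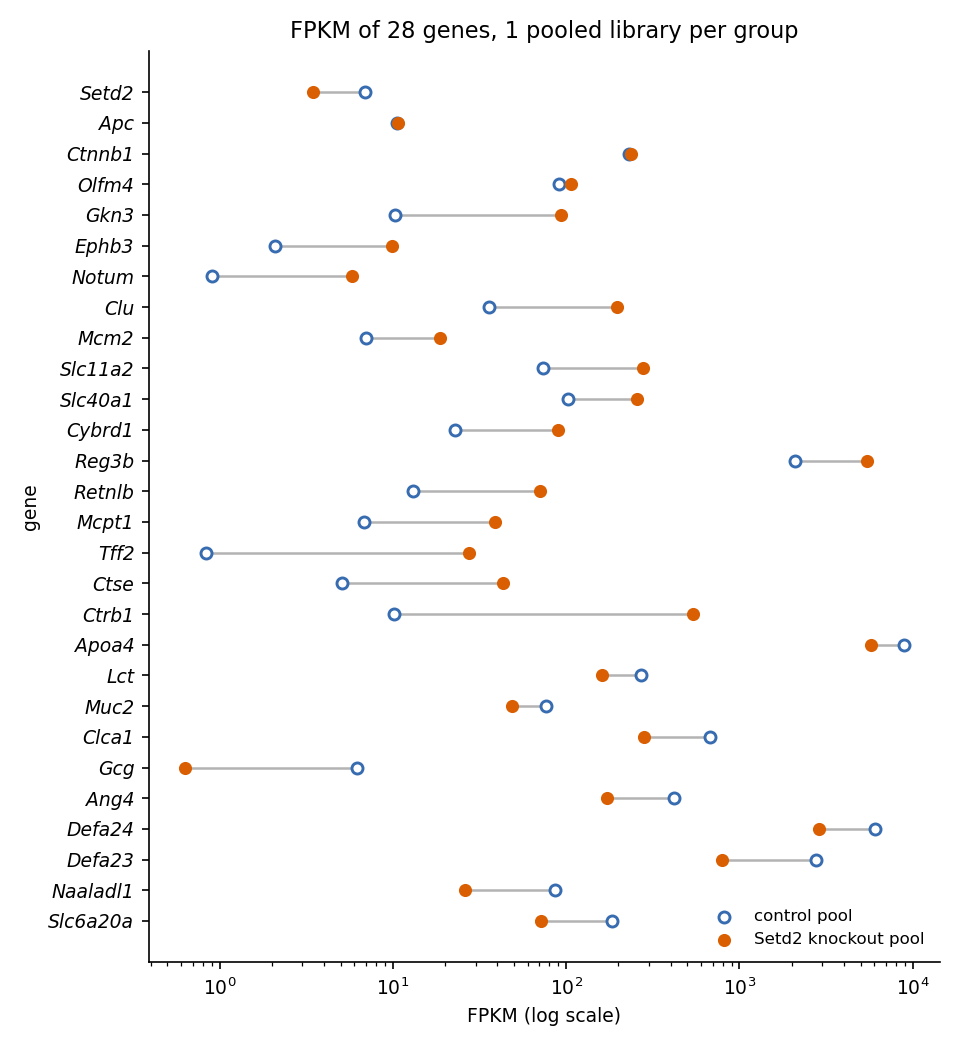
FPKM in the control pool and in the knockout pool (x axis, log scale) for 28 genes named in the text (y axis), with 1 library per pool and no error to draw. Setd2 sits lower in the knockout pool, and Clu, Slc11a2 and Gkn3 sit higher.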

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

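The minimum of 50 expected counts, the removal of the lists of other tissues and the removal of short genes were chosen after the results were seen; the other alternatives were set before. The Setd2 ratio stayed within its counting interval under the planned pseudocounts, filters and scalings. The numbers of higher and lower genes stayed at 369 and 170 without a filter, which holds by construction, since a called gene must reach an FPKM of 1. Numbers of genes at least 2-fold higher and lower were 699 and 282 with a pseudocount of 0.1, 758 and 301 with 0.01, 191 and 84 with a filter of FPKM 5, and 98 and 34 at 4-fold or 1062 and 459 at 1.5-fold, where the changed condition itself accounts for the difference. They were 216 and 80 with at least 50 expected counts, and 102 lower genes had an interval that excluded 1 and 108 were left without genes shorter than 300 nt, again from fewer genes. After rescaling to TPM 613 genes were higher; the values then grow while the pseudocount stays. The goblet median was -0.00705 when scaled by the median ratio, which by construction shifts all genes alike and left its percentile at 51.2. The proximal median turned to 0.0393 without a filter, 0.00187 with TPM and 0.141 as a mean; the colon median to 0.0447 without a filter and 0.0532 with TPM; the median of enteric neurons and glia to -0.00902 and -0.0180; and that of B and plasma cells to 0.134 with a filter of FPKM 5; the cause was not tested. Of 515 list values under alternatives 441 kept their direction and call, 37 gained a call, 13 lost it, 16 without a call changed sign (of these the Hox and Cdx list gained a call without a filter) and 8 lost a call and changed sign; 24 of 52 lists kept both under all alternatives run on them. Of 1953 values of the 257 named genes, 1883 kept direction and call and 0 reversed among called genes. The share of higher genes among those past 2-fold ranged from 64.8% to 72.2% under the scalings. The deposited table holds no comparison by the authors, so that alternative was not run. No paired analysis was possible because each group had 1 library. Depth limits what a single gene shows: 298 of the 369 higher and 102 of the 170 lower genes had counting intervals that exclude 1.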

Other observations

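The gene lists of these first paragraphs were written after the values had been seen, so their counts are descriptions and not independent evidence. Genes that mark fetal or regenerating intestinal epithelium were higher in the knockout pool, with 13 of 16 measured genes at least 2-fold higher, 0 lower and a median log2 ratio of 1.67 (95% interval 1.10 to 2.02). Besides Clu and Anxa1 they include Spp1, osteopontin (22.83 FPKM against 2.89 in the control pool), Mdk, midkine (17.88 against 2.58), Igf2bp3, a fetal RNA binding protein (4.12 against 0.26), Marcksl1 (26.07 against 6.67), S100a6 (178.3 against 72.25) and Krt7, a keratin of ducts (69.23 against 23.97). Of this list 4 genes are in a fixed list too, and 3 of the 13 higher genes had a control FPKM below 1. The pancreas, stomach and added gastric gland lists were higher in the same pool, with medians of 4.38, 1.49 and 2.22. Genes of iron handling had 4 of 11 at least 2-fold higher, 0 lower and a median of 0.40 (0.08 to 1.91); Fth1, the ferritin heavy chain, was at 5180 FPKM against 3591.

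Further genes of gastric glands formed a list apart from the fixed stomach list. Of 7 measured members 7 were at least 2-fold higher, with a median of 2.22 (1.30 to 3.98), but 4 had a control FPKM below 1. Those 4 counted as measured only through the knockout pool. Members include Anxa10 (32.28 FPKM against 1.11), the gland mucin Muc6 (6.45 against 0.6) and the transcription factor Pitx1 (20.76 against 3.09). On chromosome 4, a pair of neighbouring genes of different families was lower, of which Dffb was chosen after its values were seen. A430005L14Rik (153957237 to 153961925) was at 2.49 FPKM against 20.14, and Dffb, a nuclease of apoptosis (153964447 to 153975121), at 1.34 against 6.73. Pla2g2a, of which C57BL/6 mice carry a defective allele with little mRNA, lies on the same chromosome (start 138831857) and was at 53.51 FPKM against 8.27. Clcn4, a chloride transporter, was at 3.51 FPKM against 17.79 and H2-Bl, a class I gene of the major histocompatibility region, at 177.5 against 521.9; both were chosen after their values were seen.

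Among the tests below, those on islet hormones and on neighbouring genes were set before the results were seen, though the handling of gene families, tandem clusters and direction in the latter was settled after a first run; the others were chosen after the results were seen. Exocrine pancreas transcripts were higher in the knockout pool for 21 of 25 genes. Reads shared between paralogs would leave genes with whole counts unmoved, but of the 18 members with whole expected counts in both libraries 14 (77.8%) were at least 2-fold higher, which argues against them as the whole cause. Pancreatic tissue collected with the intestine may account for the pattern, and its islets would bring hormone transcripts: these added up to 7 expected counts in the knockout pool and 6 in the control pool, with 1 and 0 for insulin, too few to decide. Acinar regulators, in a list written after the values were seen, were higher for 4 of 6 measured genes (median 1.27, interval -0.24 to 2.06). All 4 had a control FPKM below 1, so they counted as measured only through the knockout pool. The ratio of summed counts was 0.892, or 2.90 (2.23 to 3.78) without Spink1, which is abundant in both pools. Expression of acinar or gastric genes by the epithelium after loss of Setd2 stays open as well and was not tested.

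Stem cell and Wnt target lists were higher and the enterocyte list lower. A lower share of enterocytes alone would raise all other cell types alike, but 6 of 10 cell type lists (goblet, Paneth, tuft, T cell, B and plasma cell, smooth muscle) had intervals wholly below that of the stem cell list. More proximal intestine in the knockout pool could not be told apart from the genotype: the proximal list had a median of -0.15 (-0.62 to 0.89), an interval that includes 0. Loss of Setd2 may raise crypt and Wnt target genes or the number of cells that express them, as may a different load of adenomas in the 3 mice of each pool, and neither was tested.

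Alpha-defensin transcripts were lower in the knockout pool. Reads shared among the defensin genes would leave their sum in place, but the summed counts of the cluster had a ratio of 0.428 (0.421 to 0.434). Fewer Paneth cells would lower Paneth markers outside the cluster as well. The markers outside had a median of -0.32 (-0.91 to 0.99) and a ratio of summed counts of 0.747 (0.732 to 0.762). Because the interval of the median includes 0, the explanation stays open. The upper limit of that interval is the value of Clps, which is in the pancreas list too, so it weighs little against fewer Paneth cells. Chromosome segments of another strain in 1 of the pools could place changed genes of different families side by side. In the data 15 neighbouring pairs were found against a median of 7 in 10000 random placements (percentile 99.77). The percentile was 99.43 for the 14 pairs without Rnase1 and Ang4, which are of 1 family, and 99.52 for the 10 pairs changed in the same direction. With the tandem clusters kept in, pairs changed in the same direction were at percentile 100. Pairs with both genes inside the defensin cluster were left out before counting. That 0 of the 15 pairs lay beside the cluster therefore says little about the defensins. Neighbours regulated together would give the same excess of pairs. A lower defensin expression after loss of Setd2 stays open beside these and was not tested.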
